A study of Mus musculus with 6 samples.

How the data were processed

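The values were the raw UMI counts per gene and cell barcode deposited by the authors in 1 table of 24904 genes and 44994 barcodes. A UMI is a random tag that marks 1 captured RNA molecule, so that copies made by PCR count once. Drop-seq captures single cells in droplets with barcoded beads and reads the 3' ends of their transcripts. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and aligned with STAR 2.4.0 to the mouse genome build mm10. The annotation, the counting strand and the choice of barcodes were not stated. The shallowest barcode in the table had 416 UMIs. Of the gene symbols, 23020 were found in GENCODE vM21 (GRCm38), which gave the positions, and RefSeq GRCm38.p6 gave the synonyms. Of the 201 genes chosen by the rule below, 22 overlapped an exon of another gene on the same strand and 54 on the other strand.

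Barcodes with at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes were taken as cells, which 27544 barcodes met. Doublets were called by setting each cell beside artificial pairs: 635 cells with a score of 0.75 or more among 50 neighbours were removed, and 26909 remained. In simulated pairs, this caught 60.5% of those made from different classes and 17.1% of those made within a class. Cells were clustered on log values centred and scaled within each batch, with 1000 variable genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1. Over the clustering of all cells and that of the cone bipolar-like cells, 1355 genes were used. The genes of the result lists and a random set of genes, 12985 together, were held out of the clustering, so that their tests do not reuse the values that made the clusters.

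Clusters took their names from marker genes. A class name needed a mean log2 of its markers over the other clusters of at least 1. At least 3 markers had to be at 50 CPM (UMIs per 1e6 UMIs of the same sum of cells) or more with a log2 of at least 1 each. At least 2 had to be among the cluster's top 10 genes, and more than from any other class. A cluster with no class at a mean log2 of 1 or more was called cone bipolar-like when Otx2, a transcription factor of bipolar cells and photoreceptors, reached 500 CPM. Clusters that met neither rule were left unnamed. Cone bipolar clusters were called ON when Isl1 and Grm6 together reached 500 CPM, with Isl1, Grm6 and Trpm1 each at 50 CPM or more. They were called OFF when Isl1 and Grm6 together stayed under 300 CPM and at least 3 OFF markers were at 50 CPM or more. These CPM limits were set after the clusters had been seen. The names are marker-based, since the labels give no cell types.

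For each library and class, the raw counts of its cells were summed, with at least 10 cells per sum. Sums were tested with edgeR 4.0.16 (filterByExpr, TMM normalization, quasi-likelihood F test) in R 4.3.3, with the library as a block in every contrast between classes. Calls are at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Log2 fold changes are from the fit with their standard errors. CPM values given as group means are means over libraries with the SD, scaled to the UMIs of the genes tested, adjusted by TMM. CPM of single libraries (as in the figure of Xist, Ddx3y, Hopx and Fos), of whole libraries, of cells set apart by Xist or Y-linked UMIs and of limits for a count of 0 are scaled to the plain UMI total, so the 2 kinds differ. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated per list. Values per library (shares, depths) were compared by a two-sided exact permutation test over the 15 splits of 6 libraries into 4 and 2, whose smallest p is 0.0667, so no such comparison could pass 0.05. Cells were clustered with Python 3.11.15, igraph 0.11.9 and leidenalg 0.10.2. DESeq2 1.42.0 was an alternative.

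Genes were named by a rule fixed before the data were examined. Per contrast and direction, it took the 6 genes with the largest change among those past the test, with at least 50 CPM in the higher group, the same direction in every library (for batches, no overlap between them), held out of the clustering and outside the marker lists. From each list it took the 2 members with the smallest p and the most abundant member not past the test. Each cone bipolar cluster gave the 2 genes with the largest fold over the second highest cluster, among genes held out of the clustering, outside the marker lists, past the test and at 50 CPM or more. Chosen after their values were seen were Nyx, Gpr179 and Gnao1 between rod and cone bipolar-like cells, Nyx and Rgs7 between ON and OFF cells, and Hsp90aa1, Hspa8, Hopx and Fos in Müller glia-like cells.

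The tests were tested on simulated data, with 200 changed genes per contrast. At a fold of 2, they recovered 98.5% of changed genes between rod and cone bipolar-like sums, 93.9% between ON and OFF, 85.7% across clusters, 82.8%, 92.4% and 78.5% between batches in rod bipolar-like, cone bipolar-like and Müller glia-like sums, and 38.1% for the difference of batch differences. Of the calls, between 1.5% and 8.4% were false. Intervals and limits for a count of 0 (3 counts) cover counting error only.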

Results

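The series profiled single cells of the mouse retina at postnatal day 17, sorted for the green fluorescence of the Vsx2-GFP line, whose reporter marks bipolar cells and Müller glia. Bipolar cells are the interneurons that carry photoreceptor signals to the inner retina, and Müller glia are the radial glia of the retina. There were 6 Drop-seq libraries, with replicates 1 to 4 in batch 1 and replicates 5 and 6 in batch 2. The libraries held between 4197340 and 15653963 UMIs. The mean total was 5061058 ± 680400 (SD, n = 4) in batch 1 and 14613308 ± 1472000 (SD, n = 2) in batch 2. Between 2980 and 3732 cells per library were kept in batch 1, and 7001 and 6295 in batch 2. The median depth of a kept cell was 1136 ± 103 UMIs (SD, n = 4) in batch 1 and 1248 ± 37.5 (SD, n = 2) in batch 2 (exact permutation p = 0.2). Thinned to 800 UMIs per cell, a kept cell had a median of 584 ± 1.29 genes in batch 1 and 604 in batch 2 (exact permutation p = 0.0667). The labels do not say whether the libraries came from separate animals, so every p-value measures the spread between these samples, part or all of which can be technical.

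The cells fell into 10791 rod bipolar-like, 12429 cone bipolar-like, 2941 Müller glia-like, 292 rod photoreceptor-like, 240 amacrine-like and 48 cone photoreceptor-like cells, with 168 left unnamed. Rod bipolar cells receive input from rods and cone bipolar cells mainly from cones. Rod bipolar-like cells made up 50.7% ± 0.577 (SD, n = 4) of cells in batch 1 and 29.3% ± 0.656 (SD, n = 2) in batch 2, a difference of -21.4 percentage points. Cone bipolar-like cells went from 38.7% ± 1.11 to 53.9% ± 0.009, and Müller glia-like cells from 8.84% ± 0.612 to 13% ± 0.693. Amacrine-like cells went from 0.31% ± 0.066 to 1.48% ± 0.155 and rod photoreceptor-like cells from 0.98% ± 0.274 to 1.19% ± 0.121. For the rod bipolar, cone bipolar, Müller glia and amacrine shares, every library of 1 batch lay on the same side of every library of the other, which gave the smallest possible p (0.0667, exact permutation). The shares of a library have a fixed sum, so a lower share of 1 class raises the shares of the others. The rises of the cone bipolar and Müller glia shares are thus not separate from the rod bipolar fall. Shares with rod bipolar-like cells left out were not tested. The rod photoreceptor share did not separate the batches (exact permutation p = 0.4). At clustering resolution 2, the rod bipolar difference was -11.9 points and the cone bipolar difference 5.8 in place of 15.3, since 1566 batch 1 and 267 batch 2 cells of the rod bipolar-like class lay in clusters that took the name cone bipolar there, 1444 and 244 of them in 1 cluster.

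**Figure D1:**
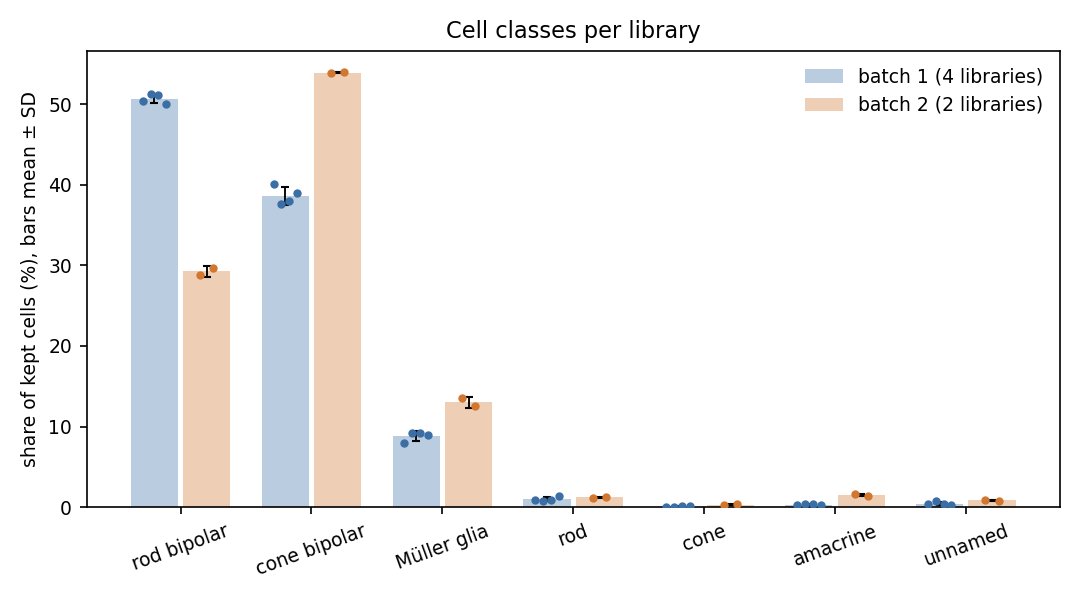
Share of kept cells (%) in each cell class, with a point per library and bars for the mean ± SD of batch 1 (n = 4) and batch 2 (n = 2). Rod bipolar-like cells went from 50.7% to 29.3% and cone bipolar-like cells from 38.7% to 53.9%.

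The first gene comparison asked which transcripts set rod bipolar-like cells apart from cone bipolar-like cells, 2 classes that share the line's reporter. Rod bipolar-like cells had more Lrrtm4, a leucine-rich repeat adhesion protein of synapses (chromosome 6, 80018877 to 80810143), at 289 ± 35.4 against 6.58 ± 1.83 CPM (SD, n = 6), a log2 fold change of 5.49 ± 0.0935 (SE). Kcne2, an accessory subunit of potassium channels (chromosome 16, 92292389 to 92298129), was at 512 ± 56 against 13.2 CPM (5.33 ± 0.0706), and Adrb1, the beta-1 adrenergic receptor (chromosome 19, 56722199 to 56733113), at 556 ± 68 against 17 CPM (5.01 ± 0.067). Ano3, of the anoctamin family (5.08 ± 0.174), Strip2 (4.60 ± 0.0626) and Kcnip2, a subunit of A-type potassium channels (4.56 ± 0.104), were higher too. Cone bipolar-like cells had more Reln, the secreted matrix protein reelin (chromosome 5, 21884454 to 22344702), at 126 ± 28.5 against 2.29 CPM (-5.68 ± 0.14), and more Cdh9, an adhesion cadherin (chromosome 15, 16728756 to 16857094), at 204 ± 13.3 against 4.51 CPM (-5.36 ± 0.131). Cacna1g, a T-type calcium channel (-5.70 ± 0.209), Nxph1, a secreted ligand of neurexins (-5.66 ± 0.178), Areg, a ligand of the EGF receptor (-5.66 ± 0.222), and Ptprt, a receptor phosphatase (-5.37 ± 0.204), were the others. Nxph1 was also higher in OFF than in ON cone bipolar-like cells, and Areg in ON than in OFF cells, as given below. Each of these 12 genes moved the same way in all 6 libraries, with adjusted p between 2.3e-32 and 3.15e-20.

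Partners of the mGluR6 cascade, through which ON bipolar cells answer glutamate, were higher in rod bipolar-like cells: of 12 tested, 7 were higher, 1 lower and 4 not past the test, with a mean log2 fold change of 0.95, the mean given for each list (camera adjusted p = 2.06e-06, and adjusted p = 0.0941 with an estimated correlation). The members past it included the regulator Rgs7 (2.09), the orphan receptor Gpr179 (1.46) and the G protein subunit Gnao1 (1.27), while nyctalopin, Nyx, was lower (-0.85). The list also holds Lrrtm4, the largest rise named above, and its median was 0.34. Cone bipolar-like sums pool ON and OFF cells, and these partners were lower in OFF cells, as given below. Part of the difference can thus come from the OFF cells. Mitochondrially encoded transcripts were higher as a group: 15 of 15 rose, among them mt-Cytb (0.83 ± 0.0313) and mt-Nd4 (0.74 ± 0.0304). The mean was 0.68 (adjusted p = 1.11e-05, and adjusted p = 0.0601 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 48 of 88 higher, 12 lower and 28 not past the test, 49 and 12 adjusted over the list alone. The mean was 0.15 (adjusted p = 0.00684, and adjusted p = 0.0941 with an estimated correlation). Ndufa4 (1.05) and Cox8a (0.65), subunits of the respiratory chain, were among the higher ones. Of 20 immediate early and dissociation-response genes, 10 were higher, 4 lower and 6 not past the test. The mean was 0.74 (adjusted p = 0.019, and adjusted p = 0.196 with an estimated correlation). Nr4a1, an orphan nuclear receptor, stood at 3.80 ± 0.141 and the chaperone Dnaja1 at 1.82. The size of the difference went with the batch. In batch 1 libraries, these genes summed to 3566 to 3935 CPM in rod bipolar-like and 2726 to 2985 CPM in cone bipolar-like cells. In replicates 5 and 6 of batch 2 they summed to 2278 and 2152 against 2015 and 1990 CPM, a smaller gap.

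Many neurotransmitter receptors were lower in rod bipolar-like cells. Ionotropic glutamate receptors and their auxiliary subunits had 10 of 13 lower, 2 higher and 1 not past the test. The mean was -1.88 (adjusted p = 7.1e-05, and adjusted p = 0.0601 with an estimated correlation). Gria2, an AMPA receptor subunit, was at 66.8 ± 8.9 against 1107 ± 193 CPM (-4.02 ± 0.0641), and Cacng2, an AMPA receptor auxiliary subunit, stood at -3.65. Between ON and OFF cells, 8 of 13 tested members of this list were lower in ON cells and 2 higher (mean -0.26). Cacng2 was among the lower ones there too. Part of the difference can thus come from the OFF cells, as for the mGluR6 partners. GABA and glycine receptors had 11 of 14 lower, 2 higher and 1 not past the test, 12 and 2 adjusted over the list alone. The mean was -1.67 (adjusted p = 0.000143, and adjusted p = 0.0601 with an estimated correlation); Gabrb1 (-4.24) and Gabbr2 (-5.26) fell. Among other neurotransmitter receptors, 10 of 17 were lower, 4 higher and 3 not past the test. The mean was -2.26 (adjusted p = 0.0102, and adjusted p = 0.0843 with an estimated correlation); the dopamine receptor Drd1 was at 5.31 against 225 CPM (-5.28 ± 0.133). That list's name patterns also took in HtrA proteases and Adrbk kinases. With these left out, a step chosen after the values were seen, 8 of 13 were lower and 3 higher (adjusted p = 0.00615, and adjusted p = 0.0804 with an estimated correlation).

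Ion channels and synaptic proteins also differed. Calcium and sodium channels had 10 of 18 lower, 5 higher and 3 not past the test. The mean was -1.54 (adjusted p = 0.00684, and adjusted p = 0.0843 with an estimated correlation): the T-type channel Cacna1h stood at -5.34 and the auxiliary subunit Cacna2d3 at 2.09. Calcium-binding proteins had 14 of 18 lower and 4 higher. The mean was -1.08 (adjusted p = 0.0371, and adjusted p = 0.153 with an estimated correlation). That call ended without replicate 6 (adjusted p = 0.0522). The calmodulin gene Calm1, at 28106 against 4094 CPM (2.78 ± 0.0303), and Pcp4, which binds calmodulin (2.16), were among the 4 higher ones. Ribbon synapse and vesicle release genes had 21 of 35 lower, 10 higher and 4 not past the test, 22 and 10 adjusted over the list alone. The mean was -0.83 (adjusted p = 0.0101, and adjusted p = 0.0941 with an estimated correlation), with Unc13c (-4.52), a priming factor, and Cplx4 (-5.28), a complexin, lower. Potassium channels had 21 of 37 lower and 12 higher (adjusted p = 0.676), and neuropeptides and secreted signals had 17 of 26 lower and 7 higher (adjusted p = 0.712), among them Chgb, a granin of secretory granules, higher at 5097 against 543 CPM (3.23 ± 0.0357). Cytosolic ribosomal proteins had 13 of 76 higher and 12 lower, 11 and 10 adjusted over the list alone (adjusted p = 0.676).

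Many adhesion proteins and transcription factors were lower. Synaptic and immunoglobulin adhesion genes had 58 of 85 lower, 16 higher and 11 not past the test. The mean was -1.61 (adjusted p = 3.65e-07, and adjusted p = 0.0941 with an estimated correlation): Cadm3 fell (-2.78) and Cntnap2 rose (2.17). Adhesion genes were also lower in ON than in OFF cells, as given below, so part of this can come from the OFF cells. Cadherins and protocadherins had 23 of 54 lower, 9 higher and 22 not past the test. The mean was -1.001 but the median -0.025 (adjusted p = 0.000291, and adjusted p = 0.0693 with an estimated correlation), with Pcdh9 lower (-4.52). Transcription factors of bipolar development had 30 of 42 lower, 8 higher and 4 not past the test, 30 and 9 adjusted over the list alone. The mean was -1.92 (adjusted p = 1.1e-10, and adjusted p = 0.0843 with an estimated correlation), with Nfia (-4.03) and Meis2 (-4.76) lower. Of markers of other cell types, the 3 tested cone photoreceptor markers were lower (mean -3.43, adjusted p = 4.6e-09). The cone photoreceptor list holds Gngt2 and the rod list Gngt1, each among the top 10 genes of a cone bipolar-like cluster. Lower values of these lists thus need not reflect photoreceptor RNA. As lists, the others were not past the test of camera. Rod photoreceptor markers had 5 of 13 lower and 1 higher (adjusted p = 0.363), amacrine markers 3 of 3 lower (mean -1.10, 0.363) and Müller glia markers 3 of 12 higher and 2 lower (0.91).

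In all, edgeR called 5760 of 10621 genes between rod and cone bipolar-like sums, 2797 higher and 2963 lower, from sums of 1339348 to 5217638 UMIs. Outside the clustering genes, 5115 of 9640 were called. Batch 1 alone gave 5140 calls, of which 4785 were shared with the full set, and batch 2 alone gave 5373, of which 4473 were shared and 3 had the opposite sign.

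The second gene comparison set ON against OFF cone bipolar-like cells, which respond to light increments and decrements. ON cells had more Gnat3, the G protein gustducin, at 61.8 ± 21.3 against 0.65 CPM (SD, n = 6; log2 5.86 ± 0.313). Also higher were Col1a2, a fibrillar collagen chain (5.79 ± 0.216), Smoc2, a secreted matrix protein (5.78 ± 0.322), and Ednrb, an endothelin receptor, at 122.6 ± 29.1 against 2.23 CPM (5.68 ± 0.202). Chodl (5.31 ± 0.211) and Areg (5.16 ± 0.233) were the others. OFF cells had more Ebf1, a transcription factor (chromosome 11, 44617317 to 45008091), at 90.3 ± 21.5 against 0.91 CPM (-6.51 ± 0.247), Nxph1 at 265 ± 26.3 against 3.93 CPM (-6.13 ± 0.134), and Fezf1, a zinc finger transcription factor (-5.83 ± 0.278). Lamp5 (-5.62 ± 0.154), Wfdc2 (-5.47 ± 0.157) and Postn, the matrix protein periostin (-5.31 ± 0.235), were lower in ON cells too. Each moved the same way in all 6 libraries, with adjusted p between 8.84e-38 and 6.82e-21.

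The mGluR6 partners were higher in ON cells, with 6 of 10 higher, 1 lower and 3 not past the test, 7 and 1 adjusted over the list alone. The mean was 0.96 (adjusted p = 3.17e-06, and adjusted p = 0.0572 with an estimated correlation). Gpr179 was at 910 ± 57 against 146 ± 21.4 CPM (2.66 ± 0.0579), Nyx at 2.4 and Gnao1 at 1.42, while Rgs7 was lower (-0.32). Nuclear genes of oxidative phosphorylation had 43 of 88 higher, 3 lower and 42 not past the test, 51 and 4 adjusted over the list alone. The mean was 0.13 (adjusted p = 1.87e-07, and adjusted p = 0.0572 with an estimated correlation): Atp5g3 rose by 0.39 and Cox6b2 fell (-1.44). Adhesion genes had 40 of 80 lower, 19 higher and 21 not past the test, 40 and 20 adjusted over the list alone. The mean was -0.46 (adjusted p = 0.00142, and adjusted p = 0.149 with an estimated correlation), with the axon guidance ligand Slit2 at 32.4 against 766 CPM (-4.59 ± 0.0706) and Ncam2 at -5. Ionotropic glutamate receptors had 8 of 13 lower and 2 higher. The mean was -0.26 (adjusted p = 0.0628), and the list passed the test without replicate 1 (adjusted p = 0.0393), without replicate 4 (0.0342) and without replicate 5 (0.041). With an estimated correlation, adjusted p was 0.401 with all libraries, and 0.422, 0.44 and 0.388 without these. Cacng2 (-4.54) and Grin2b (-3.26), a subunit of NMDA receptors, were among the lower ones. Other neurotransmitter receptors had 8 of 17 lower and 4 higher (mean -0.61, adjusted p = 0.111, and adjusted p = 0.401 with an estimated correlation; without replicate 5, 0.0125 and adjusted p = 0.388 with an estimated correlation), with the nicotinic receptor subunits Chrnb3 (-4.17) and Chrna4 (-3.48) lower. With the HtrA proteases and Adrbk kinases left out of that list, 6 of 13 were lower and 4 higher (mean -0.31, adjusted p = 0.447). The transcription factor list went both ways (19 of 42 higher, 15 lower, 21 and 16 adjusted over the list alone, adjusted p = 0.523), with St18 (4.93) and Neurod2 (4.67) higher in ON cells; its mean of -0.15 and its median of 0.14 differed in sign.

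In total, 2713 of 9608 genes were called between ON and OFF sums, 1314 higher and 1399 lower, and 2329 of the 8701 outside the clustering genes, from sums of 398701 to 3556206 UMIs. Batch 1 alone gave 1882 calls (1757 shared) and batch 2 alone 2748 (2120 shared, 1 with the opposite sign).

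**Figure D2:**
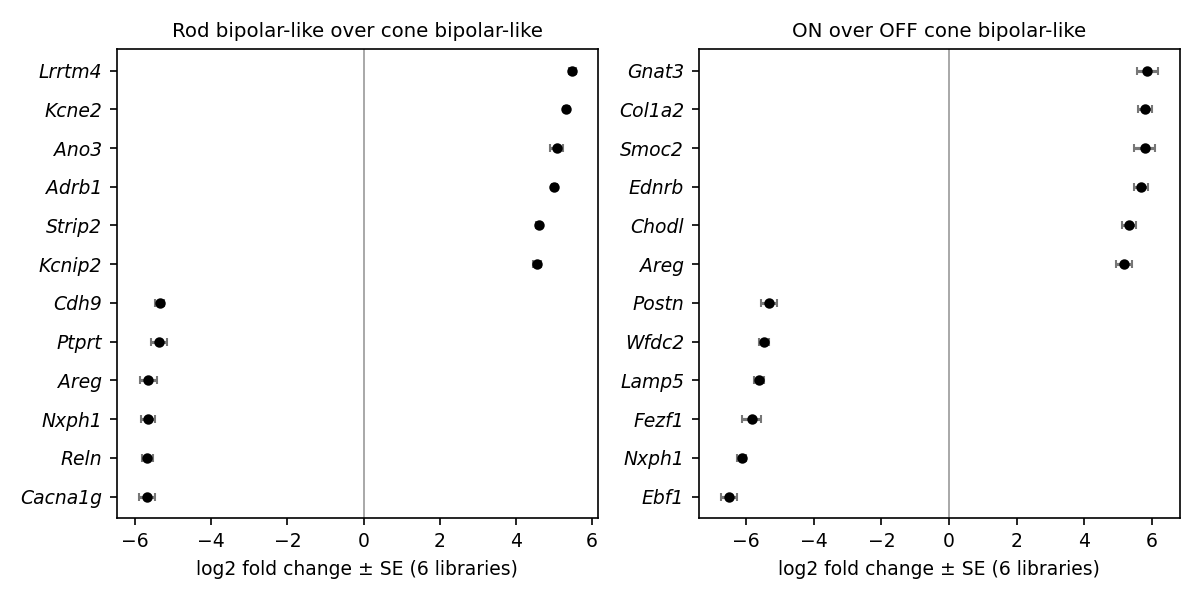
Log2 fold change ± SE over 6 libraries of the 12 genes named for rod against cone bipolar-like cells and of the 12 named for ON against OFF cone bipolar-like cells. Values run from -5.70 (Cacna1g) to 5.49 (Lrrtm4) in the first and from -6.51 (Ebf1) to 5.86 (Gnat3) in the second.

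Clustered again, cone bipolar-like cells gave 11 clusters, and the third gene comparison asked which genes mark each. Among ON clusters, cluster 1 (2272 cells, with markers of type 5A) had the most Dapl1, at 350 ± 57.3 CPM (SD, n = 6) or 10.6 times the second highest cluster, and Cyp2j9, a cytochrome P450 (123.2 CPM). Cluster 2 (1841 cells, no type name) had the most Areg, at 576 ± 206 CPM or 66.4 times the second, and Sema3e, a secreted guidance protein, at 275 ± 33.3 CPM. Cluster 3 (1767 cells, type 7 markers) had Gnat3 at 265 ± 68.5 CPM, 107 times the second, and Cacng5 (79.6 CPM). Cluster 4 (1683 cells, type 6 markers) had Lect1, chondromodulin, at 1141 ± 249 CPM, 12.4 times the second, and Gm7854 (105 CPM). Cluster 10 (517 cells, type 5D markers) had the transcription factor Irx3 at 325 ± 77.1 CPM, 81.2 times the second, and Cplx2, a complexin (403 CPM). Cluster 11 (246 cells, markers of types 8 or 9) had the protocadherin Pcdh11x at 191 ± 39.2 CPM, 17.3 times the second, and Rbfox3, an RNA-binding protein (217 ± 116 CPM).

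Among OFF clusters, cluster 5 (1194 cells, type 3B markers) had Gng2, a G protein subunit (226 CPM, 28.9 times the second), and Calml4 (157 CPM). Its Col11a1, a listed type 4 marker, was at 220 CPM, against 28 CPM in cluster 7, the second highest. Of the other type 4 markers, Grik1 is shared with type 3B, and Kcnip3 (18.9 CPM) and Vsx1 (37.1 CPM) were low. No cluster took the type 4 name, so cluster 5 may also hold type 4 cells. Clusters 6 (1061 cells) and 7 (802 cells) both carried type 1 markers: cluster 6 had Wfdc2 at 596 ± 57.7 CPM, 12.9 times the second, and Hs3st2, a heparan sulfate sulfotransferase (154 CPM), and cluster 7 had Fezf1 at 322 ± 42.5 CPM, 30.6 times the second, and Etv1 (104 CPM). Cluster 8 (524 cells, type 3A markers) had Irx5 at 469 ± 261 CPM and Adrb1 at 243 ± 97 CPM, 13.9 times the second cone bipolar cluster. Cluster 9 (522 cells, type 2 markers) had Ebf1 at 629 ± 112 CPM, 46.9 times the second, and the potassium channel Kcna1 (206 CPM). Across clusters, 3621 of 6280 genes were called, 3160 of the 5605 outside the clustering genes, from sums of 19178 to 922418 UMIs. Batch 1 alone gave 2334 calls and batch 2 alone 4047, and 5774 were called without the filter on low counts.

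**Figure D3:**
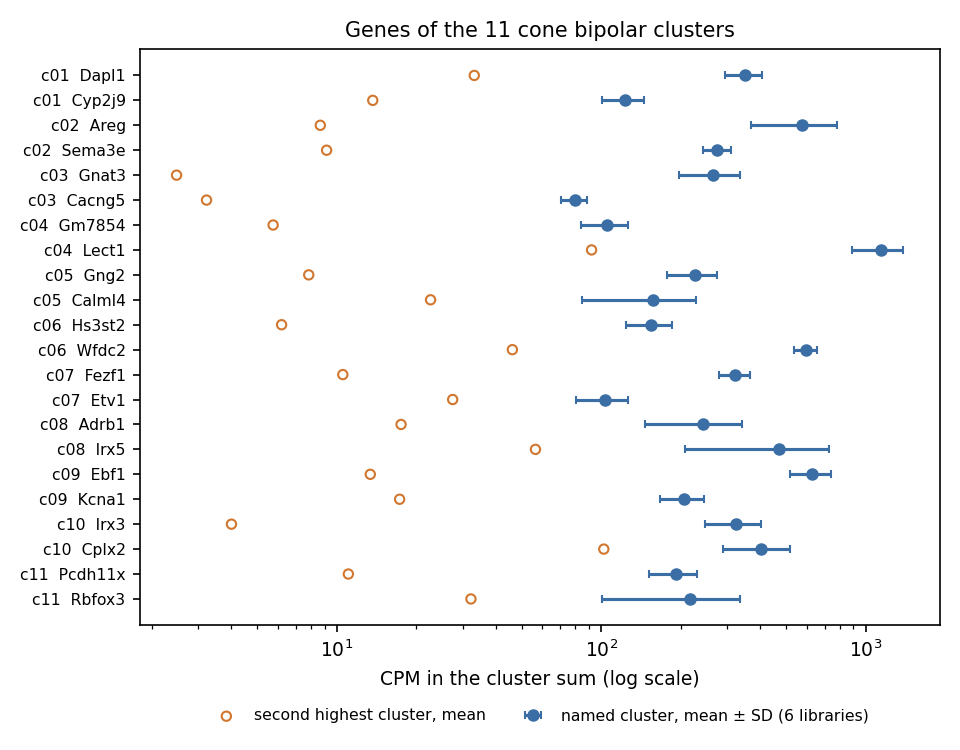
CPM (log axis) of the 2 genes named for each of the 11 cone bipolar clusters, with filled points for the mean ± SD of the named cluster over 6 libraries and open points for the mean of the second highest cluster. Gnat3 in cluster 3 lies 107 times above the second and Etv1 in cluster 7 lies 3.78 times above it.

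The batches are the only sample groups in the labels, which state no purpose for them. In rod bipolar-like cells, Xist, the RNA of the inactive X chromosome, was at 0.11 CPM in batch 1 (SD 0.226, n = 4) and 2690 ± 145 CPM in batch 2 (SD, n = 2). The Y-linked Ddx3y went from 146 to 6.69 CPM (-4.46 ± 0.171) and Kdm5d from 60.8 to 2.94 (-4.34 ± 0.232). Hopx, a homeodomain-only cofactor (chromosome 5, 77086988 to 77115121), went from 758 ± 57.2 to 4.97 ± 3.71 CPM, a log2 of -7.19 ± 0.169 (adjusted p = 1.8e-23). The 4 batch 1 libraries lay between 692 and 813 CPM against 7.61 and 2.35 in batch 2. Other named genes were listed at 0 in 1 batch: Platr17 (541 CPM), Smim10l1 (369), Snhg20 (342), Zfp638 (237) and NCBP2-AS2 (116) had UMIs in batch 2 alone, and Zfml (230), Prss22 (106) and Stxbp3a (68.3) in batch 1 alone. A count of 0 allows up to 0.357 CPM over the batch 1 sums and 0.551 over the batch 2 sums. Several of these are pairs of symbols of 1 gene, such as Zfml and Zfp638, a point taken up with the genes seen in 1 batch.

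Ribosomal protein genes fell in batch 2 in rod bipolar-like cells: 48 of 78 were lower, 1 higher and 29 not past the test, 54 and 3 adjusted over the list alone. The mean was -0.54 (adjusted p = 1.04e-16, and adjusted p = 0.266 with an estimated correlation). Rpl3 stood at -2.92 and Rpl26 at -1.57, though such genes share reads with many pseudogenes. Whether a difference in gene annotation between the batches, taken up below, moved their counts was not tested. Immediate early and dissociation-response genes had 9 of 22 lower, 2 higher and 11 not past the test. The mean was -0.49 (adjusted p = 7.19e-08, and adjusted p = 0.147 with an estimated correlation): Fos went from 400 ± 33.7 to 75.6 ± 6.39 CPM (-2.41 ± 0.099), and the chaperone Hspa8 fell too (-1.40). Transcription factors of bipolar development had 8 of 31 higher, 0 lower and 23 not past the test, 11 and 1 adjusted over the list alone. The mean was 0.34 (adjusted p = 0.0144, and adjusted p = 0.266 with an estimated correlation), with Prdm8 (0.81) and Sox4 (1.05) higher. Markers of other cells rose as well. Rod photoreceptor markers had 10 of 13 higher and 1 lower (11 and 1 adjusted over the list alone, mean 1.07, adjusted p = 5.82e-07, and adjusted p = 0.103 with an estimated correlation), and Müller glia markers had 8 of 12 higher and 0 lower (10 and 1 adjusted over the list alone, mean 0.64, adjusted p = 0.000346, and adjusted p = 0.145 with an estimated correlation). The 14 rod photoreceptor markers took 0.0726% ± 0.00352 of the UMIs of these cells in batch 1 and 0.0943% in batch 2 (exact permutation p = 0.0667), against 0.686% and 0.459% in barcodes outside the cell filter (exact permutation p = 0.533).

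edgeR called 2079 of 10519 genes between the batches in rod bipolar-like cells, 1004 higher and 1075 lower. Without replicate 5 there were 977 calls, without replicate 6 there were 1023, each with 1 library left in batch 2, and DESeq2 gave 1182. Most batch 1 cells of this class (4765 of 6902) lay in a cluster with a median of 995 UMIs and most batch 2 cells (2244 of 3889) in one with a median of 1536, and the deeper cluster alone gave 1477 calls, of which 1250 were shared.

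In cone bipolar-like cells, Xist went from 0.15 to 2706 ± 38.2 CPM (SD, n = 2), Hopx from 171 ± 20.1 (SD, n = 4) to 13.5 CPM (-3.65 ± 0.137), Ddx3y from 127 to 10.4 (-3.62 ± 0.143) and Kdm5d from 52.8 to 5.33 (-3.31 ± 0.196). Rpl3, a ribosomal protein gene, fell from 146 to 25.4 CPM (-2.54 ± 0.149). Listed at 0 in batch 1 were Platr17 (414 CPM in batch 2), Smim10l1 (386), Snhg20 (266), Zfp638 (261) and NCBP2-AS2 (117), and listed at 0 in batch 2 were Zfml (249 CPM in batch 1) and Prss22 (94.5). Limits for a count of 0 were 0.455 CPM in batch 1 and 0.303 in batch 2. Ribosomal protein genes had 36 of 78 lower, 5 higher and 37 not past the test, 39 and 6 adjusted over the list alone. The mean was -0.34 (adjusted p = 3.81e-08, and adjusted p = 0.584 with an estimated correlation): Rps2 fell (-2.31) while Rpl29 went from 0.93 to 51.8 CPM (5.76). The limits given for ribosomal protein genes in rod bipolar-like cells, pseudogenes and annotation, hold here too. Transcription factors of bipolar development had 19 of 43 higher, 1 lower and 23 not past the test, 22 and 1 adjusted over the list alone. The mean was 0.30 (adjusted p = 7.87e-05, and adjusted p = 0.584 with an estimated correlation), with Sox4 (0.88) and Lhx4 (0.65) higher. The immediate early list was not past the test here (4 of 19 higher, 4 lower, 4 and 6 adjusted over the list alone, adjusted p = 0.375). Rod photoreceptor markers (9 of 13 higher, 1 lower, mean 0.59, adjusted p = 0.00123) and Müller glia markers (6 of 12 higher, 0 lower, 8 and 0 adjusted over the list alone, mean 0.54, adjusted p = 0.00163) rose, with adjusted p = 0.103 and adjusted p = 0.282 with an estimated correlation. The share of rod marker UMIs was 0.192% in batch 1 and 0.213% in batch 2 (exact permutation p = 0.133). Gngt1, 1 of the rod markers, was among the top 10 genes of a cone bipolar-like cluster with 584 batch 1 and 1274 batch 2 cells. Part of the rod marker UMIs of this class can thus come from bipolar cells, and part of their rise from the mix of clusters. There were 2513 calls among 10924 genes, 1271 higher and 1242 lower, with 1333 by DESeq2. Leaving out replicate 5 or 6 leaves 1 library in batch 2. The mix of cone bipolar clusters differed between batches: of 5257 batch 1 and 7172 batch 2 cells, cluster 2 held 590 and 1251, and cluster 1 held 1077 and 1195. Part of these calls can come from that mix, since the batches were not compared within a cluster.

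**Figure D4:**
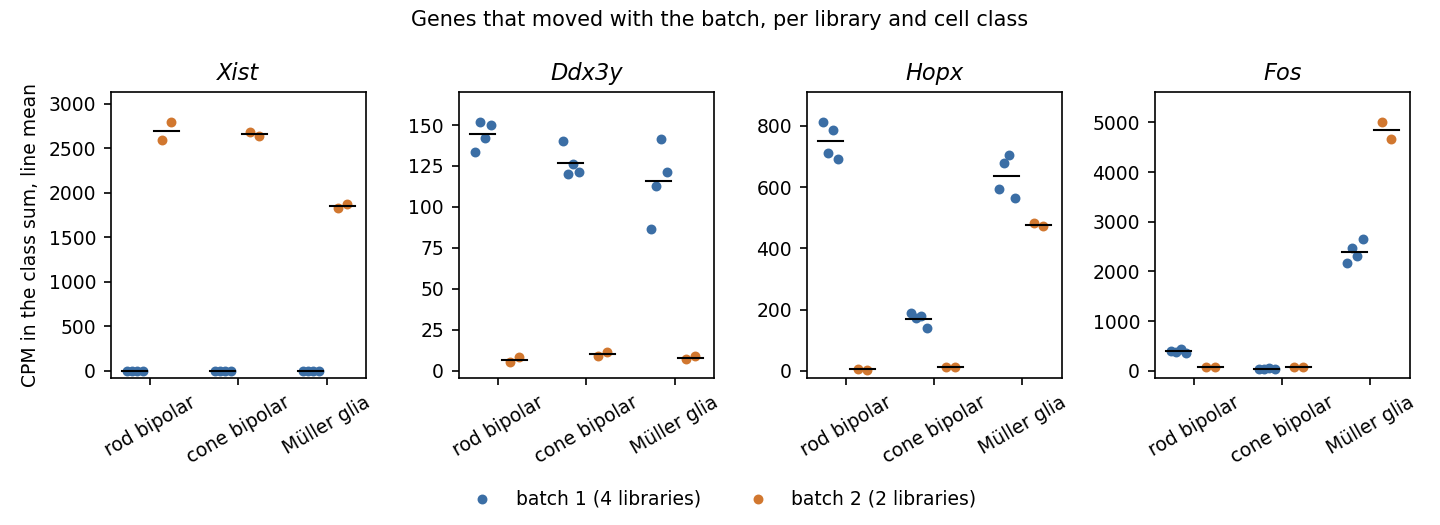
CPM of Xist, Ddx3y, Hopx and Fos in the sums of rod bipolar-like, cone bipolar-like and Müller glia-like cells, with a point per library and a line at the mean of batch 1 (n = 4) and batch 2 (n = 2). These CPM are scaled to the UMI total of each sum over all genes, without TMM. The means in the text are scaled to the genes tested with TMM factors, so they differ. Hopx lies between 692 and 813 CPM in batch 1 rod bipolar-like cells, at 7.61 and 2.35 in those of batch 2, and at 483 and 472 in batch 2 Müller glia-like cells.

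In Müller glia-like cells, immediate early genes rose in batch 2. Fosb, a partner in AP-1 transcription factors, went from 84.9 ± 16 (SD, n = 4) to 685 ± 91.4 CPM (SD, n = 2), a log2 of 2.98 ± 0.135, and Ier2 from 535 ± 35.2 to 1782 ± 81.7 (1.74 ± 0.0874). Of the immediate early and dissociation-response list, 16 of 23 rose, 2 fell and 5 were not past the test, 19 and 3 adjusted over the list alone. The mean was 0.91 (adjusted p = 5.04e-46). This call held with an estimated correlation (adjusted p = 0.00832). The 2 that fell were the chaperones Hsp90aa1 (-0.68) and Hspa8 (-0.90). Ribosomal protein genes had 28 of 61 lower, 1 higher and 32 not past the test, 39 and 2 adjusted over the list alone. The mean was -0.51 (adjusted p = 1.29e-16, and adjusted p = 0.148 with an estimated correlation), with Rps2 (-2.59 ± 0.246) and Rpl26 (-1.62) lower. Again, pseudogenes and a possible difference in annotation limit what these ribosomal protein counts show. Transcription factors of bipolar development had 5 of 25 higher, 0 lower and 20 not past the test, 6 and 0 adjusted over the list alone. The mean was 0.18 (adjusted p = 0.0265, and adjusted p = 0.188 with an estimated correlation). Sox2, a factor of glial and progenitor cells, rose from 449 ± 19 to 901 ± 93.1 CPM (1.00 ± 0.0959), and Sox4 stood at 0.63, a call that ended without replicate 5 (adjusted p = 0.247) and with DESeq2 (0.126). Xist went from 0 to 1985 ± 29.9 CPM and Ddx3y from 120 to 8.74 (-3.79 ± 0.28), and the pseudogene Rps26-ps1 fell from 63.6 to 10 CPM (-2.66 ± 0.342).

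Listed at 0 in batch 1 Müller glia-like cells were Smim10l1 (324 CPM in batch 2), Zfp638 (154), Snhg20 (149), NCBP2-AS2 (132) and Stxbp3 (69.3), and listed at 0 in batch 2 were Zfml (130 CPM in batch 1), Stxbp3a (94.5) and Prss22 (66.4). The limits for a count of 0 were 1.94 and 1.21 CPM. Rod photoreceptor markers had 5 of 7 higher and 0 lower (6 and 0 adjusted over the list alone, mean 1.14, adjusted p = 3.66e-06, and adjusted p = 0.0817 with an estimated correlation), and their share of UMIs went from 0.0248% to 0.053% (exact permutation p = 0.0667). Müller glia markers had 3 of 13 higher and 0 lower (5 and 2 adjusted over the list alone, mean 0.17, adjusted p = 0.0024, and adjusted p = 0.0817 with an estimated correlation). There were 601 calls among 7382 genes, 306 higher and 295 lower, from sums of 276005 to 1304255 UMIs, with 259 without replicate 5, 303 without replicate 6 and 257 with DESeq2.

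The last comparison tested whether the batch difference itself differed between Müller glia-like and rod bipolar-like cells. Hopx fell in rod bipolar-like cells (-7.19) and far less in Müller glia-like cells, from 661 ± 68.3 to 512 ± 7.43 CPM (-0.37), a difference of 6.85 ± 0.171 (F = 1602). Fos fell in rod bipolar-like cells (-2.41) and rose in Müller glia-like cells from 2498 to 5184 CPM (1.05), a difference of 3.5 ± 0.095. Bhlhe40, a clock-linked repressor, differed by 3.42 ± 0.234, Dusp1, a phosphatase of MAP kinases, by 3.23 ± 0.15, and Nr4a1 by 2.84 ± 0.332. Gadd45b, a stress-response gene, differed by 5.44 ± 0.785, on few UMIs in Müller glia-like cells, and by 8.62 without replicate 2. These 6 had adjusted p of 2.72e-09 or less and also passed with DESeq2. In the other direction were Tox3 (-1.81 ± 0.505), H2-K1 (-1.57 ± 0.303), Tsc22d4 (-1.35 ± 0.307), Olfm1 (-1.17 ± 0.266), Zeb2 (-1.14 ± 0.259) and Igfbp5 (-1.10 ± 0.295), with adjusted p between 8.32e-05 and 0.0284, and none of these passed with DESeq2 (adjusted p from 0.112 to 0.9999). Without replicate 5, the calls of Tox3 (adjusted p = 0.369), Tsc22d4 (0.431), Olfm1 (0.0745) and Igfbp5 (0.0681) ended. Without replicate 6, those of Tox3 (0.11), Olfm1 (0.0612), Zeb2 (0.306) and Igfbp5 (0.461) ended. Batch 1 libraries mattered too: the Tox3 call ended without replicate 1 (adjusted p = 0.181), 2 (0.11) or 3 (0.246), that of Olfm1 ended without replicate 2 (0.0646), and that of Igfbp5 without replicate 2 (0.116) or 4 (0.114). Without replicate 4, Tox3 stood at -3.29.

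The immediate early list had 13 of 23 members with a higher batch difference in Müller glia-like cells, 0 lower and 10 not past the test, 18 and 0 adjusted over the list alone. The mean was 1.42 (adjusted p = 2.98e-24), and the call held with an estimated correlation (adjusted p = 0.00514). Calcium-binding proteins had 0 of 19 past the test of edgeR, with 6 at an unadjusted p below 0.05, 1 higher and 2 lower adjusted over the list alone, and a mean of -0.48 (adjusted p = 0.0285, and adjusted p = 0.434 with an estimated correlation), a call that ended without replicate 2 (adjusted p = 0.229), 4 (0.124) or 6 (0.181). Müller glia markers had 4 of 13 lower and 1 higher (8 and 1 adjusted over the list alone, mean -0.47, adjusted p = 1.36e-07, and adjusted p = 0.127 with an estimated correlation). In all, 152 of 10475 genes were called, 101 higher and 51 lower, with 16 by DESeq2, 81 without the library block, 72 with cells of at least 700 genes, 44 without replicate 5 and 60 without replicate 6. Over the 6 contrasts, 26 of 96 tests of the fixed lists passed at the preset correlation. In 16 of the 96, none of them past the test, the list's median, mean and test differed in sign. With the correlation estimated, the immediate early list in the Müller glia-like batch comparison and in the difference of batch differences were the 2 that passed.

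**Figure D5:**
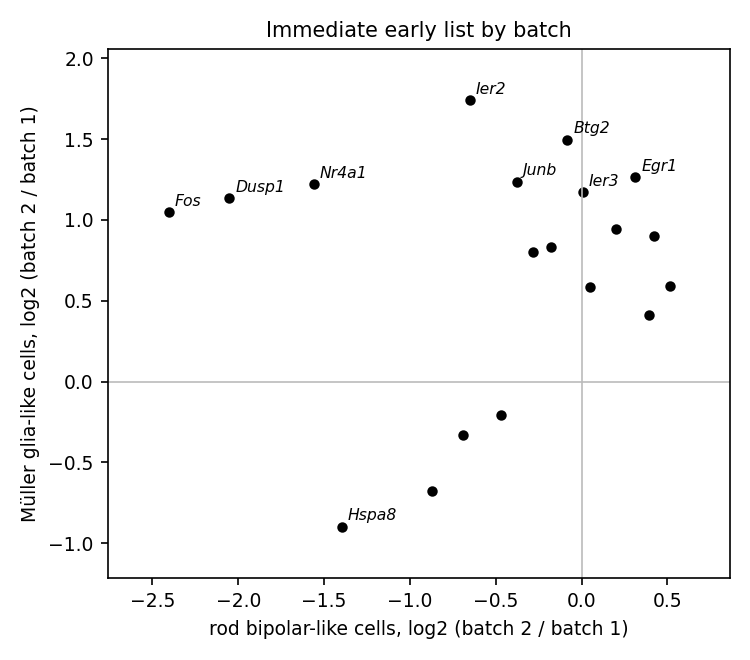
Log2 of batch 2 over batch 1 for the genes of the immediate early and dissociation-response list that were tested in both classes. Rod bipolar-like cells are on the horizontal axis and Müller glia-like cells on the vertical axis, with a point per gene. Genes tested in 1 class alone, such as Fosb, are not shown. Fos lies at -2.41 and 1.05, and Hspa8 fell in both (-1.40 and -0.90).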

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

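The thinning of cells to 1 depth, the search for gene synonyms and the test of RNA from other cells were tests chosen after the results they address had been seen, and the other tests in this part were chosen before.

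Rod bipolar-like cells were a smaller share of batch 2 than of batch 1, by -21.4 percentage points. The cell filter as the whole source is argued against: with each of the 44994 barcodes given its closest class, the difference was still -17 points. That pool includes the kept cells, which differed by -22.4 points on the same measure. Barcodes under 500 genes differed by -8.89 points and those over 10% mitochondrial by -5.12, so the filter can account for a part. Depth per cell is argued against as well, since the difference was -21.4 points (-21.42) with every cell thinned to 800 UMIs, which left out 1820 cells of batch 1 and 1842 of batch 2. The sex of the animals is argued against. Batch 2 cells with a Y-linked UMI and no Xist UMI held 21% rod bipolar-like cells (82 of 391 cells, Wilson 95% interval 17.2 to 25.3). Batch 1 cells with a Y-linked UMI held 54% (52.6 to 55.3), a difference of -33 points. Batch 2 cells with an Xist UMI and no Y-linked UMI held 31% (30.1 to 31.8), so the 2 groups within batch 2 differed as well. How the retinas were dissociated and sorted in each batch stays open and cannot be told apart from a difference between the animals, since the batches share no library.

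Among genes with at least 100 UMIs in 1 batch, 21 had none in batch 2 and 54 had none in batch 1. A candidate explanation is that the batches were counted against 2 versions of the gene annotation: 81% of the genes seen in batch 1 alone (17 of 21) had a RefSeq synonym among those seen in batch 2 alone, and all 17 pairs lay within 2-fold. Zfml with Zfp638 and Stxbp3a with Stxbp3 are such pairs, and Trp53rkb was the partner of both Trp53rk and 2810408M09Rik. The other way round, 21 of the 54 genes seen in batch 2 alone had a synonym seen in batch 1 alone. Of these, Mpv17 with Mal (log2 of synonym over gene -9.285) and Ifit3b with I830012O16Rik (-1.151) lay outside 2-fold. The sex of the animals is argued against for the set, since 4.17% of the genes with a known chromosome (2 of 48) lay on X or Y. The other genes of the set, with no synonym found, stay open.

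Hopx in rod bipolar-like cells and immediate early genes in Müller glia-like cells moved with the batch, and the batch difference itself differed between these classes: 6.85 for Hopx, 5.44 for Gadd45b, 3.5 for Fos, 3.42 for Bhlhe40, 3.23 for Dusp1, 2.84 for Nr4a1 and a mean of 1.423 for the immediate early list (log2, Müller glia-like minus rod bipolar-like). The sex of the animals is argued against for Hopx, with 0 UMIs (0.0% of the batch 1 level, upper 95% limit 5.1%) in 82 batch 2 rod bipolar-like cells with a Y-linked UMI, against 732 CPM in such cells of batch 1. RNA from other cells in the droplets is argued against for the list: in batch 2, other kept cells, all barcodes and those outside the cell filter held it at no more than 19.5% of the Müller glia-like level, though the files hold no empty droplets. For the early genes in Müller glia-like cells, the test did not decide on sex: 47 cells with a Y-linked UMI in batch 2 had 1.24 times the level of such cells in batch 1 (95% interval 1.16 to 1.33, on both sides of the limit set for the test). The list stood at 13710 CPM in these 47 cells, at 11010 in such cells of batch 1, and at 23240 in batch 2 cells with Xist and no Y-linked UMI. Fos alone was at 2545 CPM (95% interval 2173 to 2963), 2393 (2276 to 2515) and 5150 in the same order. Batch 2 cells with a Y-linked UMI thus lay nearer to batch 1 than to batch 2 cells with Xist. This goes with a part for sex, on few cells, and leaves other differences between batches open. Within batch 2, sex cannot be told apart from other differences between the animals that gave these cells. The same 2 groups of batch 2 cells also differed in their rod bipolar-like share, as given above. The time from death to lysis may have differed between the batches, which the labels do not record and which was not tested.

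The calcium-binding list also differed in its batch difference, by a mean of -0.484 (adjusted p = 0.0285, and adjusted p = 0.434 with an estimated correlation). It had 0 of 19 members past the test, with 1 higher and 2 lower adjusted over the list alone, and its call ended without replicate 2, 4 or 6. Single genes that differed were Tox3 (-1.81), H2-K1 (-1.57), Tsc22d4 (-1.35), Olfm1 (-1.17), Zeb2 (-1.14) and Igfbp5 (-1.10), none of them past the test with DESeq2. Replicate 2 stood apart from the other batch 1 libraries in Xist, at 0.4494 CPM in rod bipolar-like and 0.59 CPM in cone bipolar-like sums, each from 1 UMI where the others had 0. These were 2 of the 62 sets of values examined for an isolated library, and chance gives about 1 in 20. Outside the cell filter, 28.6% ± 0.955 (SD, n = 2) of batch 2 barcodes had over 10% mitochondrial UMIs, against 1.13% ± 0.254 (SD, n = 4) of batch 1 barcodes.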

How the results depend on the processing

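The settings limited to 1 batch, without genes seen in 1 batch, and with the deeper rod bipolar cluster alone were chosen after the data had been seen. Of the answers to the comparisons, 153 kept their direction, their side of the threshold or, for counts, stayed within 1.5 times; the rod bipolar share difference ran from -22.46 (batches not centred) to -11.93 (resolution 2). DESeq2 lowered the batch counts to 1182 (rod bipolar-like), 1333 (cone bipolar-like), 257 (Müller glia-like) and 16 (difference of batch differences). That last count was 72 with at least 700 genes per cell and 81 with no replicate block. The count across clusters was 5774 with no filter on low counts and 2334 in batch 1 alone. Leaving out each library gave 977 to 2079, 1089 to 2563, 259 to 594 and 44 to 125 calls for the same 4 results. Leaving out replicate 5 or 6 leaves 1 library in batch 2, assumed to vary like the others. With an estimated correlation, 2 list calls were past the test in place of 26.

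These reversed: Lrit1 (0.186), Ntm (0.114) and St18 (-0.14) between rod and cone bipolar-like cells and Kcnma1 (-0.125) between ON and OFF in batch 2 alone, Dnaja1 between ON and OFF (0.453) and Pcp4 between batches in cone bipolar-like cells (-0.586) at resolution 2, mt-Rnr2 between batches in cone bipolar-like cells (-0.055) at a 5% mitochondrial limit, and the unnamed share (-0.12) when thinned. The cone photoreceptor share difference was 0.0 with at least 700 genes, a 5% limit or thinning, where no cluster took that name. For the others the cause was not tested. Among single genes, lists and shares, 6786 values kept their side, 73 newly passed and 196 no longer did, of which 29 with DESeq2, 27 without replicate 5 and 29 without replicate 6. At the depth and number of libraries here, 38.1% of simulated changes at a fold of 2 were recovered for the difference of batch differences.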

Other observations

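The comparison of annotation versions was a test chosen after the results had been seen; the splits reported in this part were chosen before.

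Amacrine-like cells (240) and photoreceptor-like cells (292 rod and 48 cone) were present beside the classes that the reporter line marks. Hopx, chosen here after its values were seen, was abundant in Müller glia-like cells of both batches, at 661 ± 68.3 CPM (SD, n = 4) and 512 ± 7.43 CPM (SD, n = 2). In batch 1 alone, rod bipolar-like cells reached that level. Adrb1, named for rod bipolar-like cells, also stood at 243 ± 97 CPM in cone bipolar cluster 8, and Areg, higher in cone bipolar-like cells, was mostly in cluster 2 (576 ± 206 CPM).

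Over whole libraries, Xist was at 0 to 0.941 CPM in batch 1 and at 2152 and 2188 CPM in batch 2, and 4 Y-linked genes together were at 488 to 515 CPM in batch 1 and at 62.4 and 61.6 CPM in batch 2. In cells of at least 1000 UMIs in batch 2, 9.52% of the 294 with a Y-linked UMI had an Xist UMI (median depth 1452 UMIs), against 90.3% of the 8783 others (median depth 1521 UMIs). In batch 1, 0.02% of 8618 such cells had one.

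Other splits of the sums into groups of 6 and 6, across libraries, were drawn for the comparisons of classes, and cluster names were exchanged within libraries for the clusters. For rod against cone bipolar-like sums, 1 of 59 splits, the real one, reached 5760 calls, and the highest of the others gave 2058. For ON against OFF, 1 of 59 reached 2713 calls, and the highest other gave 0. For the cone bipolar clusters, 1 of 24 draws reached 3621 calls, and the highest other gave 53. The classes and clusters were made from the expression of the same cells, so these splits cannot exclude chance as the source of the counts.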
